A study of Homo sapiens with 5 samples.

How the data were processed

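Total RNA from muscle biopsies of the vastus lateralis, a thigh muscle, was measured as 1 pool, which the labels call pool 3 of insulin sensitive samples. The pool was hybridised to 5 Affymetrix oligonucleotide array designs: Hu35K subA, Hu35K subB, Hu35K subC, Hu35K subD and HuFL. On these arrays a gene or expressed sequence tag is measured by a probe set, a group of short oligonucleotides. The deposited values are intensity values on a linear scale, per the labels and the values themselves: whole numbers, of which 23.1% to 32.6% per array lay below 0. How the authors computed and scaled the intensity values, and with which software, is not given in the sources used here. Values below 0 can arise where a background or mismatch signal is subtracted, but the step was not stated. No genome build was named, and no coordinates are given.

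With 1 pool there was no group comparison and no biological replicate, so no p-value was computed. The 5 arrays hold mostly different probe sets, and their number limits the precision. Other pools, including any of insulin resistant samples, were not analysed here. No column of per-sample values was left unused.

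Probe sets were paired with genes through the platform annotation tables. Control probe sets (59 per array) were set aside, which left 42548 probe sets. Of these, 29711 had 1 gene symbol, 857 had several and 11980 were not named by the tables. Symbols were checked through gene identifiers against the RefSeq gene table of assembly GRCh38.p14, used for names only: 29636 probe sets matched, and 75 kept the symbol of the annotation table. Gene statistics used the probe sets with 1 symbol, which covered 14746 genes. In the gene lists, 1 older symbol was replaced by its current name (MYLPF by MYL11).

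The background level of an array was the 99th percentile of the sizes of its negative values, over all probe sets other than controls. A gene was counted as above background if at least 1 of its probe sets exceeded the level of its array. The signal percentile of a probe set was its rank within its array, and a gene took the median over its probe sets. Ranks are of hybridisation signal, which depends on the probes, and are no order of transcript abundance. For 26 gene lists, holding 465 distinct genes, the share of genes above background and the median signal percentile were placed among 10000 random lists of as many genes, matched on the number of probe sets per gene (1, 2, 3, or 4 and more). A list's position is the percent of random lists with a lower value, counting ties at 0.5 weight. Positions of at least 95 or at most 5 were called high or low. These positions describe this pool and are no test across samples.

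The gene lists, the background rule and the alternatives were fixed before the data were examined. Genes named in the text followed a rule fixed at the same time: the 5 highest probe sets with 1 symbol on each array, the 3 genes of highest signal percentile in each list with the first 2 in alphabetical order of its genes not above background, 8 genes of insulin action and muscle biology whatever their value, and the 5 listed genes whose probe sets differed most on the log2 scale, with values under background set to the level of their array. Genes named outside this rule are marked as named after their values were seen. Genes linked to the Y chromosome were left out of the named genes.

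For control probe sets shared by the 5 arrays, the SD of log2 signal over arrays was computed where all 5 values were above 0, with Spearman's rho between arrays. In the search for arrays far from the others, 55 of these probe sets were tested, and the remaining ones are not reported here. The ratio of signal at the 3′ end to that at the 5′ end was taken for the GAPDH and ACTB controls, all of which were above background on the 5 arrays. For genes with 1 HuFL probe set and at least 1 Hu35K probe set, values under background were set to the background level, and the HuFL log2 signal was set against the mean Hu35K log2 signal.

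Alternatives fixed beforehand were other background levels (the 95th percentile, the size of the lowest value, and fixed values of 100 and 200) and equal trimmed means (2% off each end). The probe sets with a suffix letter s, f, i or r, here all called a cross-hybridisation suffix whatever the letter marks, were also removed together. Further alternatives were other rules from probe set to gene, and leaving out each array. After the data were seen, 3 more were added: values of exactly 0 on HuFL treated as not measured, scaling on the 9 spike probe sets (bacterial and phage transcripts whose names are those of hybridisation controls), and random lists matched also on having a HuFL probe set.

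The list statistics were tested on simulated data, with the real values shuffled within each array over 14746 genes. Of 400 random lists of 20 genes, 5.25% were called high by share above background and 4.50% by signal. Such shares follow from placing random lists among random lists. They check the calculation only, and not how often lists of well-studied genes would be called. For 200 genes in 10 lists, values were made positive and multiplied by 2, and 4 lists were called by share and 10 by signal. Multiplied by 4 these numbers were 9 and 10, and by 8 they were 10 and 10. Negative values thus changed sign as well, so these calls do not measure sensitivity to a rise of that fold alone. The rank correlation step returned 0.464 on 3000 simulated genes made with an expected rho of 0.483. Calculations used Python 3.11.15, NumPy 2.4.6, pandas 2.3.3, SciPy 1.17.1 and matplotlib 3.10.9.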

Results

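The muscle RNA pool was measured on 5 arrays with 42548 probe sets besides controls. Above background lay 398 of 8875 probe sets on Hu35K subA (4.48%), 399 of 8865 on subB (4.50%), 297 of 8869 on subC (3.35%), 687 of 8869 on subD (7.75%) and 459 of 7070 on HuFL (6.49%). The background levels were 1160 on subA, 263.1 on subB, 521 on subC, 568 on subD and 972 on HuFL. These shares rest on a strict level. At a fixed value of 100 they ran from 14.4% on subB to 50.2% on subA. There was 1 pool and no replicate, so every value below is a single measurement.

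The highest probe sets with 1 gene symbol, genes linked to the Y chromosome left out, included contractile, mitochondrial and ribosomal genes. On subA they were RPS27, a ribosomal protein (14739), MYL1, a fast myosin light chain (11636), MYOZ1, a Z-disc protein (11025), UQCRQ, a subunit of respiratory complex III (10911), and GAPDH (10465). On subB they were MYOZ1 (3964), PPP1R3C, a glycogen-targeting subunit of protein phosphatase 1 (3780), CHCHD10, a mitochondrial protein (3653), ATP5MC3 of ATP synthase (3461) and PDLIM3 (3318). On subC they were slow troponin T TNNT1 (7014), ANKRD23 (5977), CMYA5 (5633), calsequestrin CASQ1 (5338) and RPS15 (4913). On subD they were RPS20 (10849), the heat shock protein HSPB1 (10141), RPL41 (10034), TXNIP (9503) and HSPB6 (8900), while the highest value of any subD probe set besides controls was 11841. On HuFL they were the calcium pump ATP2A1 (16126), slow troponin C TNNC1 (15558), TPT1 (14037), MYBPC2 (13463) and TNNT1 (12895).

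HuFL held 1054 values of exactly 0, 14.8% of the array, against a mean of 20.4 probe sets at each whole number from 1 to 5 on either side. On the 4 Hu35K arrays 13 to 125 values were 0. Genes that muscle uses in bulk were among them, so a gene at 0 is described here only as listed at 0. Counts below include such genes as not above background. There were 303 genes measured on HuFL alone and listed only at 0.

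**Figure D1:**
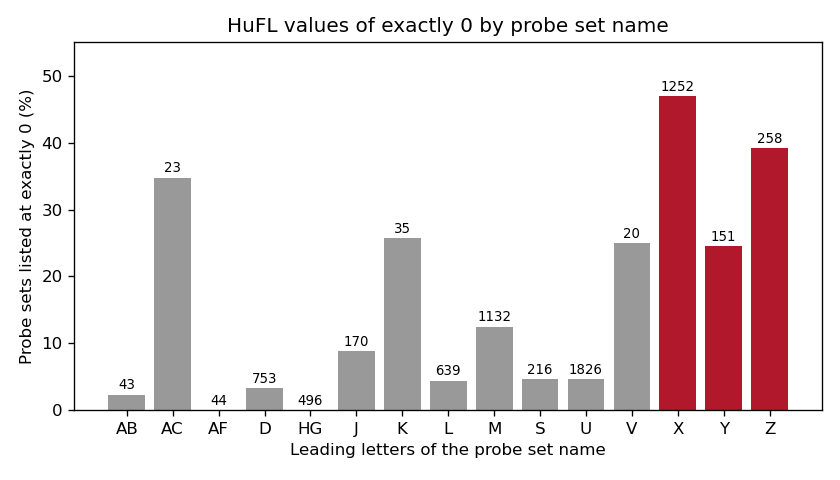
Share of HuFL probe sets listed at exactly 0 (y axis, percent) by the leading letters of the probe set name (x axis), with the number of probe sets above each bar and X, Y and Z in red. The share was 47.0% for X, 39.1% for Z, 34.8% for AC, 25.7% for K, 25.0% for V, 24.5% for Y and 12.5% for M, and 4.66% for the 1826 probe sets of letter U.

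Genes of the contractile apparatus stood high. Of 31 measured sarcomere genes 26 were above background, with a median signal percentile of 98.7. Examples were TNNC1, MYOZ1 and TNNT1. The 5 not above background included skeletal actin ACTA1, MYBPC1 and MYL2, each listed at 0 on HuFL, its single array. Genes of slow fibres were above background in 9 of 10 cases, with TNNC1, TNNT1 and MYOZ2 (1234 on subC) in front and MYL2 listed at 0. Genes of fast fibres were above background in 12 of 14 cases, led by ATP2A1, MYOZ1 and CASQ1. PVALB (180 on HuFL) and tropomyosin TPM1 were not, and the TPM1 probe sets ran from -104 on subD to 147 on the same array. Genes of both fibre types were thus above background, and no proportion between them was read. Of 14 calcium handling genes 10 were above background, among them sarcolipin SLN (8004 on HuFL). CACNA1S (346 on HuFL) and CACNB1 (324 on HuFL and 166 on subD) were not. All 4 lists lay at position 100 among random lists, by share above background and by signal. These are not 4 separate results, since most slow and fast fibre genes also stand in the sarcomere or calcium handling list. Without suffix probe sets 18 of 24 sarcomere genes and 6 of 8 slow fibre genes were above background. For fast fibres and calcium handling it was 8 of 10 and 8 of 12, and all 4 lists stayed at position 100 by share.

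Genes of energy metabolism stood high as well. In oxidative phosphorylation 44 of 47 genes were above background (median signal percentile 97.0), with NDUFA1 (10297 on subA), COX7A1 (11470 on HuFL) and ATP5ME (7114 on subA) in front and NDUFB5 (322 on subA) among the others. In glycolysis and glycogen metabolism 19 of 24 were above background (94.8), with muscle enolase ENO3 (10894 on HuFL), GAPDH and PGM1 (9863 on HuFL) in front. ENO1 (578 on HuFL) was not above background. In the citric acid cycle and mitochondrial carrier list 13 of 27 were above background (90.9), including VDAC3 (1886 on subA and 2413 on subB), VDAC1 (6071 on HuFL) and SLC25A3 (6044 on HuFL). Citrate synthase CS reached 917 on subA, under the level there, and DLAT was 1 of 3 genes listed only at 0. In fatty acid oxidation 10 of 19 were above background (89.1), including ACADM (4517 on HuFL), ECI1 (1997 on subA) and the fatty acid transporter CD36 (2056 on HuFL). ACAA2 (591 on HuFL) and ACADL were not. All 4 lists lay at position 100 by share and by signal. With the lowest value of each array as the background level, the citric acid cycle list fell to position 90.6 by share (2 of 27 genes) and the fatty acid oxidation list to 76.6 (1 of 19). On HuFL this level was 9690, the size of its most extreme negative value, against 972 at the main level. Only 0.453% of HuFL probe sets exceeded 9690.

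Genes of insulin action, the property that names the pool, were mostly within background at the main level but not at lower fixed values. Of 27 measured insulin signalling genes 4 were above background, position 51.4, and the median signal percentile of 62.6 lay at position 94.0. IRS2 reached 1522 on subA and GRB10 677 on subD. The insulin receptor INSR had 7 probe sets, from -14 on subD to 317 on subA, none above background. IRS1 reached 971 on subA and 756 on HuFL, under the levels of these arrays, and AKT1 and AKT2 reached 340 and 388 on HuFL. In glucose transport 3 of 11 genes were above background, position 90.6, with a signal position of 96.3. The insulin-regulated glucose transporter SLC2A4 gave 434 on subA and 642 and 283 on HuFL, none above background, while VAMP2 reached 641 on subD and 631 on subC. STXBP3 (499 on HuFL), NSF (431 on subD) and SLC2A1 (349 on subD) were not above background. The counts followed the background level. At fixed values of 100 and 200, 24 and 17 of 27 insulin signalling genes and 10 and 9 of 11 glucose transport genes were above it, and at the 95th percentile level 9 and 8. Without subB 2 insulin signalling genes were above background, and without subD 1 glucose transport gene. The share positions of both lists moved with the processing in both directions. Glucose transport ran from 18.9 without suffix probe sets, where no gene was above background, to 99.9 at the 95th percentile background level, with 24.9 on HuFL alone and 53.4 without subD. Insulin signalling ran from 9.99 on HuFL alone to 99.4 at a fixed value of 100, with 20.5 without subB. The signal position of insulin signalling became high on HuFL alone (98.7), without subB (99.1), subC (97.7) or subD (99.4) and with random lists matched on HuFL (95.2, chosen after seeing the data), and was 73.1 without HuFL and 72.4 by the highest probe set.

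Among regulators of muscle energy use 5 of 17 genes were above background, position 94.7, with a signal position of 96.1. They included myoglobin MB (8197 on HuFL), MEF2C (4345 on subD) and MEF2D (1228 on subA). Muscle creatine kinase CKM was listed at 0 on HuFL, its single array. PPARGC1A, a coactivator of mitochondrial genes, gave 101 on subC and 541 and 206 on subD, and ESRRA gave 281 on HuFL, none above background. Glycogen synthase GYS1 was above background at 1025 on HuFL. Hexokinase HK2 reached 223 on subA and myostatin MSTN 46 on subC, neither above background. The high signal call of this list was lost in 7 alternatives, with positions of 61.5 on HuFL alone, 92.1 by the highest probe set, 90.7 without subB and 93.5 to 93.6 without subA, subC or HuFL, and just under the bound without suffix probe sets. Its share position became high in 4 alternatives, at 95.1 without values of 0 (chosen after seeing the data), 95.4 without subC, 98.3 without subD, and without suffix probe sets.

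Ribosomal protein genes were above background in 28 of 31 cases (median signal percentile 97.7), with RPL30 (8112 on subD), RPL32 (10808 on HuFL) and RPL4 (1996 on subC) in front, and RPL13 (162 on subB) and RPL37 were not. Without HuFL 9 of 17 were above background, still at position 100 by share. Stress response genes were above background in 9 of 16 cases (82.6), led by the small heat shock proteins CRYAB (8475 on HuFL) and HSPB1 and by SOD2 (2185 on subA). ATF3 (40 on HuFL) and DNAJB1 (501 on HuFL) were not. Both lists lay at position 100 by share, and at 100 by signal.

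**Figure D2:**
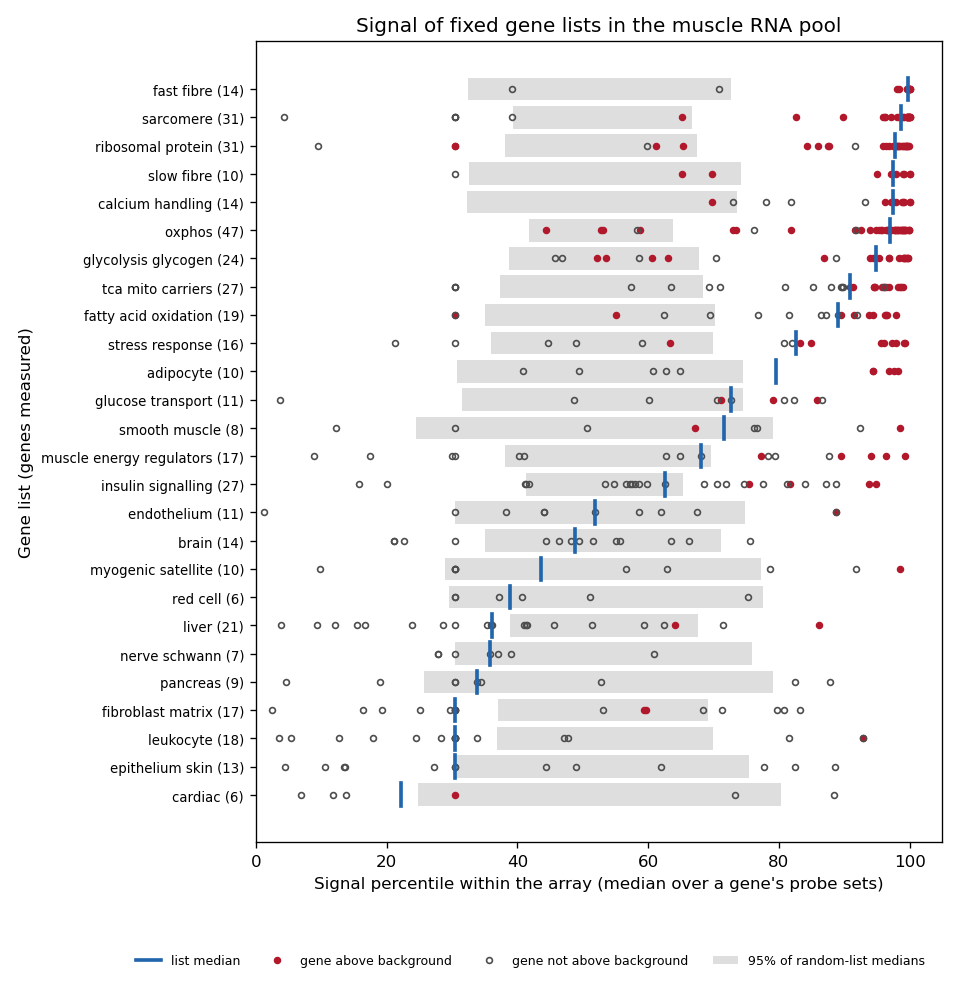
Signal percentile within the array (x axis, median over a gene's probe sets) for the genes of each list in the muscle RNA pool. Points are genes, filled red where a probe set was above background and open where none was, blue lines are list medians and grey bars hold 95% of the medians of matched random lists. The median of the fast fibre list lies at 99.8 and that of the cardiac list at 22.2, and the column of points at 30.5 holds genes listed at 0 on HuFL.

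Among markers of other cells of a biopsy, the fat cell list was the 1 list called high, and the other lists had shares above background that were not called high or low at the main level. At a fixed value of 100 the leukocyte and nerve lists were called low by share (positions 1.95 and 4.96), and at 200 the leukocyte list (1.99). Of 10 fat cell genes 5 were above background, position 99.9, and 1 of the 10 stands also in a list of the tissue itself. GPD1 (2035 on subA), PLIN1 (1348 on subD) and CFD (2883 on subA and 2302 on HuFL) were in front, and ADIPOQ (1285 on HuFL) and FABP4 (1127 on HuFL), named after their values were seen, were above background too. CIDEC (39 on subD) and leptin LEP (109 on HuFL) were not. The signal position of this list was 99.3, and it fell to 50.5 without subA and 55.6 on HuFL alone. Satellite cell and myogenic genes were above background in 1 of 10 cases, which was desmin DES (5911 on HuFL), a gene of the sarcomere list, position 56.0. VGLL2 (544 on subD) and CDH15 (288 on HuFL) were not, and 3 genes were listed only at 0. Smooth muscle genes were above background in 2 of 8 cases, position 92.7, and at 97.6 with a fixed value of 200 and 95.9 without suffix probe sets. These were DES and MYH11 (995 on subD, named after its value was seen), with LMOD1 at 829, TAGLN at 255, ACTG2 at -62 and ACTA2 listed at 0 on HuFL. Endothelial genes were above background in 1 of 11 cases, position 48.3, which was VWF (892 on subD), with NOS3 at 580 on HuFL, TEK at 223 on subA, EDN1 at 13 on subB and CDH5 listed at 0. The VWF value on subD came from a probe set with a cross-hybridisation suffix.

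Leukocyte genes were above background in 1 of 18 cases, position 22.5, which was lysozyme LYZ (1252 on HuFL), and CD3E (872), IL2RG (342), CD14 (-237) and CD2 (-55 on HuFL) were not. Their median signal percentile of 30.5 lay at position 0.275, and at 5.32 on HuFL alone. LYZ was above background only through a probe set with a cross-hybridisation suffix. Matrix genes of fibroblasts were above background in 3 of 17 cases, position 76.5, and 3 of the 17 were listed only at 0. Above background were COL1A2 (860 on subD), SPARC (773 on subD) and DCN (598 on subD), named after their values were seen. Of these, COL1A2 was above background only through a probe set with a cross-hybridisation suffix. COL4A1 and LUM gave 328 each on HuFL, COL15A1 gave 308 and both COL1A1 probe sets were listed at 0. The signal position of the matrix list was 0.225, but 36.8 without subB, 6.69 without HuFL, 51.3 by the highest probe set and 63.5 when values of 0 on HuFL were treated as not measured, an alternative chosen after seeing the data. No red cell gene of 6 was above background, position 23.2. ALAS2 reached 532 on subD, CA1 70 on subC and AHSP 69 on subD, and 2 of the 6 were listed only at 0. No nerve gene of 7 was above background, position 19.5, with MBP at most 243 on subC, GAP43 at most 126, NEFM at 4 and NEFH at 63 on subD. Positions 23.2 and 19.5 were the lowest that the red cell and nerve lists could reach by share. Neither list could thus be called low at the main level.

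Markers of other tissues had shares above background that were not called high or low at the main level, and the liver list was called low at a fixed value of 100 (4.90). Of 21 liver genes 2 were above background, AMBP (1466 on subD) and APOC3 (717 on subD), while ALB (7 on HuFL), AHSG (53 on HuFL) and F2 were not. Of 6 cardiac genes 1 was above background, the atrial and embryonic light chain MYL4 (2162 on subD), whose 3 HuFL probe sets were listed at 0. ACTC1 (571), NPPB (309) and MYL7 (-50) on HuFL were not. By share, neither the cardiac nor the smooth muscle list could be called low at the main level. The median of their random lists had no gene above background. MYL4, AMBP and APOC3 were above background only through probe sets with a cross-hybridisation suffix. The same held for muscle and housekeeping genes named earlier, among them TNNT1, MYOZ2, CASQ1, MYL1, GAPDH, ENO3, RPL30 and RPL4. On HuFL, AMBP was listed at 0 and APOC3 gave 280. Over all arrays 18.7% of probe sets with suffix f and 9.27% with suffix s were above background, against 4.10% without a suffix. None of 9 pancreas genes, 14 brain genes and 13 epithelial genes was above background. With none above, the share positions of these lists were the lowest they could reach, so none could be called low at the main level. Their highest-ranked members included SST (546), CPB1 (361) and CPA1 (59) on HuFL, SYN1 (356 on subD), MAPT (329 on HuFL) and SYT1 (291 on subA), and KRT10 (638), KRT1 (457) on subA and KRT14 (272 on HuFL). CAMK2A reached 1107 on subA, just under the level there. CEL reached 104 on subA, ENO2 -8, CDH1 23 and DSG1 -57 on HuFL. By share, the liver, cardiac, epithelial, pancreas and brain lists lay at positions 36.4, 73.0, 17.0, 21.9 and 8.66. By signal, the liver, cardiac and epithelial lists lay at 0.935, 1.39 and 3.00, the pancreas list at 11.1 and the brain list at 33.4. The liver list moved to 6.92 without subB and 11.1 without HuFL, and the epithelial list to 52.7 without HuFL, 14.4 on HuFL alone and 5.79 without suffix probe sets. By the highest probe set the cardiac list moved to 17.2. With values of 0 on HuFL treated as not measured, an alternative chosen after seeing the data, the cardiac list moved to 27.1 and the epithelial list to 7.49.

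Probe sets of the same gene often gave different values in this one RNA. The sarcoplasmic calcium pump ATP2A2 gave 8444 on subD, 131 on HuFL and 54 and -11 on subB, of which the first was above background. RPS23 gave 10510 on HuFL, 413 on subB and 91 on subC, and MDH1 gave 6185 on HuFL and 87 on subB. ATP5MC3 gave 3461, 52, 43 and 42 on subB itself, beside 5833 on HuFL, and RPS20 gave 10849 on subD beside 447 and -40 on subC. No fold between arrays is given for these genes, since their signals were not on a common level. Of 7978 genes with 2 or more probe sets, 103 had all above background, 993 some and 6882 none. Across 2508 genes with 1 HuFL and at least 1 Hu35K probe set, Spearman's rho was 0.119. For 2152 of these genes no probe set was above background, so their values were background levels. The median absolute log2 difference of 0.77 equals the log2 ratio of the HuFL and subD levels, 0.77, and so measures the levels and not the genes. Across the 79 genes measured above background on both sides rho was 0.50. Genes are not independent replicates, and arrays were not scaled here.

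Technical spread was read from 59 control probe sets shared by the arrays. Spearman's rho between pairs of arrays ran from 0.927 to 0.982. For the 36 control probe sets above 0 on all 5 arrays the median SD of log2 signal was 0.78, and 0.22 after scaling on the 9 spikes, which was added after seeing the data. The 9 spikes are among the 36, so part of this drop is fixed by the scaling. The 6 GAPDH and ACTB sets alone gave 0.21 after scaling. Controls do not give the spread of other probe sets. Over 404 others with the same name on HuFL and subA, rho was 0.412, with 4 above background on both. The trimmed mean signal of the arrays differed up to 5.83-fold, from 33.8 on subB to 197 on subA, over mostly different probe sets. On shared probe sets, the level of subA over subB was 3.26-fold for the spikes and 3.36-fold for GAPDH and ACTB. The deposited values were thus not on a common level. The 3′ to 5′ ratio of the GAPDH controls was 0.690 ± 0.0273 (SD, n = 5 arrays), and that of the ACTB controls 0.331 ± 0.0631 (SD, n = 5 arrays). Both depend on the probes as well as on the RNA, so only the spread over arrays is read.

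**Figure D3:**
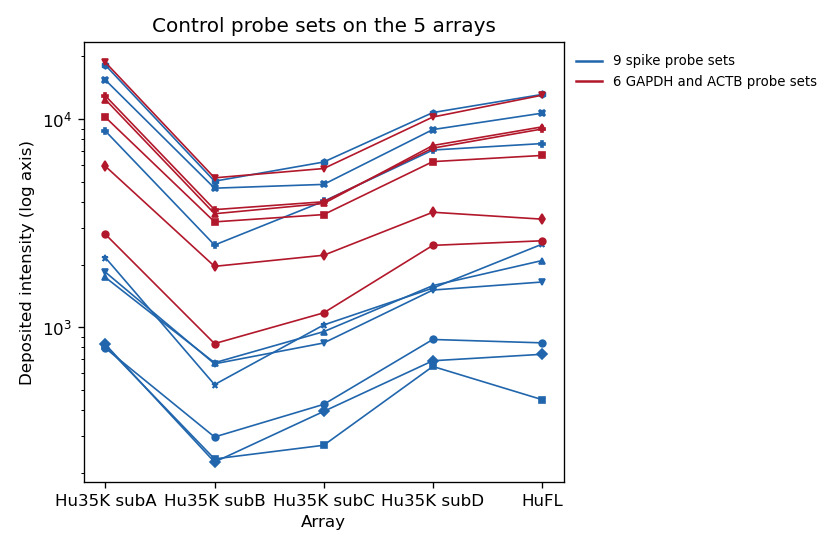
Deposited intensity (log y axis) of control probe sets on the 5 arrays (x axis), all hybridised with the same muscle RNA pool. Each line is a probe set, blue for the 9 spikes and red for the 6 GAPDH and ACTB probe sets, and the lowest value of every GAPDH and ACTB line is on subB, where the GAPDH 5′ probe set gave 5216 against 18697 on subA.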

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

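Control values in this part were scaled on the spikes unless given as deposited, a scaling and a comparison chosen after the data were seen, and the test of array brightness was chosen after its result was seen.

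Among 55 shared control probe sets tested, 4 had 1 array far from the other arrays, and chance gives about 5% of such probe sets. In the deposited values 2 of the 4 stood as far apart. None of the 4 was above background on any array. On subB a TrpnX set stood at -396.5, against -182 to -109 on the other arrays, but its deposited value of -197 lay within the -294 to -76 of the others. On subA the sense-strand BioB 5′ set stood at -260.6 (deposited -422, others 20 to 178). On HuFL the ribosomal RNA control sets (HUMRGE) stood at 419.2 for the 3′ part (deposited 591, others 60 to 292, no longer far apart) and 266.0 for the 5′ part (deposited 375, others 45 to 98).

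Outside the spikes and the GAPDH and ACTB sets, 2 control probe sets were above background on all 5 arrays. The Alu repeat set had a mean of 6818.9 ± 857 (SD, n = 5 arrays). The sense-strand set for the 3′ part of ACTB had a mean of 1707.6 ± 166 (SD, n = 5 arrays), beside 1777 for the antisense set of the same part. The sense-strand sets for the 5′ and middle parts of ACTB had means of 10.1 and 117.

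Signal was lower on subB than on the other Hu35K arrays, by 1.72-fold in unscaled trimmed mean against subC and 5.83-fold against subA. A lower brightness of the whole array could account for part of this, since each of the 9 spikes was also lower on subB. After scaling on the spikes a gap of 1.22-fold against subC and 1.79-fold against subA remained, which lies between what brightness alone and what no share of brightness would give. The size of the gap depended on the scaling. Scaled on the GAPDH and ACTB sets, not planned beforehand, the trimmed mean was 61.0 on subB, 90.9 on subC, 104 on subD and 106 on subA. This left a wider gap against subC than the spikes did. The remaining gap stays open, as subB holds other probe sets than the other arrays. No biological explanation was tested, since all arrays had the same RNA.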

How the results depend on the processing

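Values of 0 on HuFL treated as not measured, scaling on the spikes and random lists matched on HuFL were chosen after the data were seen; all other alternatives were planned. The share of probe sets above background followed the background level, as its construction requires. For subA, subB, subC, subD and HuFL in this order it was 13.2%, 10.2%, 10.5%, 16.1% and 14.2% at the 95th percentile, 1.08%, 0.925%, 1.01%, 2.72% and 0.453% at the lowest value, 50.2%, 14.4%, 21.3%, 34.2% and 39.1% at a fixed 100, and 34.7%, 6.54%, 11.0%, 21.1% and 27.5% at a fixed 200. At 100 after equal trimmed means it was 34.7%, 34.8%, 31.8%, 30.2% and 27.6%, and after spike scaling 39.7%, 27.6%, 28.6%, 29.8% and 33.4%. Without suffix probe sets subC gave 2.42% and subD 5.98%, and without values of 0 HuFL gave 7.63%. The median SD of shared controls, the spikes included, was 0.48 with equal trimmed means and 0.22 with spike scaling. Leaving out 1 array gave a lowest rho between arrays of 0.927 to 0.967, the highest without subA. The 3′ signal over the middle gave 0.990 for GAPDH and 0.581 for ACTB. The 11 lists high by share and 13 high by signal, some of which share genes, stayed within 1.5 times these numbers under all alternatives run. Low by share were 0 lists, and 3 at a fixed 100 and 1 at a fixed 200. At the main level the red cell, nerve, pancreas, brain and epithelial lists had no gene above background and still could not be called low. Low by signal were 5 lists, 3 on HuFL alone, 3 without values of 0, and 1 to 7 when 1 array was left out (1 without HuFL, 3 without subB). The matrix list turned from position 0.225 to 51.3 by the highest probe set and to 63.5 without values of 0, and the epithelial list from 3.00 to 52.7 without HuFL (2.66 to 52.7 when 1 array was left out). The rank correlation between HuFL and Hu35K was 0.50 for pairs above background, 0.190 with equal trimmed means, 0.00650 without suffix probe sets and 0.262 on ranks. The median log2 difference was 0.71 for pairs above background and 0.38 with equal trimmed means. Lists with under 3 measured genes under an alternative gave no position there. The cause of the changes in rho and in the list positions was not tested. Most probe sets lay within background on every array at the main level.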

Other observations

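The tests on values of 0 and the test of cross-hybridisation for fat cell genes were chosen after the results were seen. The test on a second list of fat cell genes was written before the values of its genes were looked at.

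Values of exactly 0 on HuFL were unevenly spread over the names of the probe sets. They made up 43.7% of 1661 probe sets named for accessions beginning with X, Y or Z and 6.06% of 5409 others, a ratio of 7.21, but this division of the names was chosen after the shares were seen, and the shares for names beginning with AC, K and V (34.8%, 25.7% and 25.0%) were above that for Y (24.5%). A placeholder in the place of missing values could be a source of the zeros and was not tested. Transcripts without signal that round to 0 are argued against: of 331 genes with all HuFL values at 0 and a Hu35K probe set, 15.4% were above background on Hu35K (exact 95% interval 11.7% to 19.8%), against 2.85% of 246 genes with HuFL values within 20 of 0 (1.15% to 5.77%). For 242 genes at 0 with X, Y or Z names the share above background on Hu35K was 16.9%, and for 80 with other names 10%. No interval was computed for these parts, so the smaller one is less certain. An earlier comparison, with all 2405 genes holding no 0, gave 11.0%. Negative values set to 0 are argued against too, since 23.1% of HuFL values were below 0, and no biological explanation was tested.

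Fat cell genes above background (5 of 10) were weighed against 2 explanations. Probe sets annotated by suffix as cross-hybridising are argued against by the 5 of 9 genes still above background without them, and cross-hybridisation of other probe sets was not tested. Fat cells within the biopsies could be a source and stay open: a second list of fat cell genes gave 1 of 14 above background, position 38.95, under the bound of 50 written beforehand as counting against fat cells, but within the 0% to 28.6% that 95% of random lists gave, a spread taken into account only after the result was seen, and its signal position was 69.4. The 1 gene was PLIN4 (2497 on subD), while SCD (546 on subD) and ADIRF (875 on subA) were not above background, all 3 named after their values were seen. An earlier form of the test counted 5 of 9 genes of the first list itself and was set aside, because it used the genes that show the pattern.

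Probe sets with the same name stood on HuFL and subA for 465 names besides controls, of which 61 were listed at 0 on HuFL. Over the other 404, Spearman's rho across probe sets was 0.412. For the 60 above 200 on both arrays the SD of the log2 difference was 0.78 after spike scaling, and 4 of the 404 were above background on both.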
